A study of Mus musculus with 28 samples.

How the data were processed

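Sorted male germ cells of mice with a working Stra8 gene (WT) and of Stra8 knockout mice (KO) were profiled by RNA sequencing. Per the labels' protocols, the mice received WIN 18,446, a blocker of retinoic acid synthesis, over 7 days. They were then collected (0 h) or injected with retinoic acid and collected 12, 18, 48, 72, 96 or 120 h later, and cells carrying the PIWIL2-eGFP reporter were sorted from the testis. Per the labels' protocols, RNA was extracted with Trizol and polyA-selected, and barcoded libraries were made with an Ion Torrent total RNA kit for an Ion Proton sequencer. The 14 groups had 2 libraries each. The labels do not say that the replicates are separate animals, so every p-value measures only the spread between these samples, which may be technical.

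Per the submitters' processing notes, Bowtie, TopHat, Cufflinks and the mouse build mm10 were used; their versions, the counting program and its use of strand were not given in the sources used here. The authors deposited read counts per gene symbol in a pair of tables, called here the first and the second count table, each with 1 library of every group. The authors also deposited a pair of tables named as FPKM. The design had assumed FPKM, but the values in these tables were CPM, counts scaled to the library total, with no division by gene length: 25 of the 28 columns equalled a count column divided by its total within 0.001 CPM. WT columns matched the same-numbered count table (14 of 14) and KO columns the other-numbered one (11 columns). The remaining 3, KO at 72, 96 and 120 h in the first CPM table, matched no count column. Their low values were whole multiples of 1 read (100% within 0.1 read) and gave totals of 4479729, 4190650 and 4122223 reads, and these are called recovered reads. Which of these columns and the count columns holds the right values for these KO groups, and which KO numbering follows the samples, was not given in the sources used here. All comparisons used the counts, with libraries numbered as in the count tables; CPM values were used in alternatives and checks only.

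The tables held 43280 features. Of these, 27 with date-like names were left out, and 39349 of the remaining 43253 matched 1 gene of the GENCODE annotation for GRCm38. Exon overlaps with neighbouring genes were computed from it. Total counts were 5752475 to 10135820 in the WT libraries and 913055 to 9507928 in the KO libraries (median of all 28, 7017729). KO libraries at 72, 96 and 120 h in the second count table had 1078460, 913055 and 1030025 reads and are called the 3 shallow KO libraries. For WT only, the first count table gave, reads outside genes: 27.1 to 33.1% had no annotated feature, 0.68 to 0.78% were ambiguous and 14.3 to 16.2% were not uniquely aligned. A count of 0 was read against a floor of 3 counts per library; floors cover counting error only.

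Counts were tested with edgeR 4.0.16 in R 4.3.3: TMM scaling, its default expression filter (17519 genes kept), 14 group means and robust quasi-likelihood tests, with Benjamini-Hochberg adjustment per comparison and a threshold of 0.05. The comparisons were KO vs WT as the mean over the 7 times and at each time, each later time against 0 h within a genotype, any change over the time course within a genotype, and genotype by time interaction. Log2 fold changes are given with their standard errors, and CPM, from TMM-scaled totals, as mean and SD; Stra8, Kit and marker levels of single libraries are given per library total. The 21 gene lists were written before the data were examined and tested with camera (limma 3.58.1) at a preset correlation of 0.01, adjusted over the 21 lists per comparison; camera was also run with an estimated correlation. The lists hold undifferentiated spermatogonia, differentiating spermatogonia, retinoic acid signalling and metabolism, meiotic prophase, DNA replication and G1/S, mitosis and G2/M, cell cycle inhibitors and cyclins D, piRNA pathway and germline, autophagy and lysosome, p53 targets, immediate early and stress, glycolysis, oxidative phosphorylation and cytosolic ribosomal protein genes. They also hold markers of Sertoli cells, Leydig cells, peritubular myoid and stromal cells, macrophages and leukocytes, endothelium, erythroid cells and spermatids. The list genes Meiosin and Ankrd31 were not matched to a table entry.

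Named genes followed a rule fixed before the data were examined. Stra8 came first. For the mean comparison, up to 15 higher and 15 lower genes were taken by fold change among those past the threshold, with a mean of at least 5 CPM in either genotype and the same sign at 6 or more of the 7 times. For KO vs WT at each time, up to 6 each way with both KO libraries on the same side of both WT libraries and 5 CPM in either group were taken, likewise 10 each way for WT and 4 each way for KO against 0 h, and 12 by smallest p for the interaction. Gene models without a gene name were counted only. Where none passed, the 3 with the smallest p were named, and a described list is represented by up to 4 genes with the smallest p. Some genes under the rule are left out for length.

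Alternatives were DESeq2 1.42.0 and its size factors in edgeR, a filter of 5 CPM in 2 libraries, no filter and an added 2-fold threshold. Others compared groups alone, left each library out, took the replicate number as a block, or left out mitochondrial and ribosomal protein genes. A further alternative was limma on log2 of the deposited CPM plus 1 or plus 0.1, with the CPM table number as block. This number crosses the KO numbers of the count tables. The deposited CPM held the values of the recovered reads in place of the 3 shallow KO libraries. Lists were also tested with fry. Alternatives added after the data were examined used the recovered reads, left out the 3 shallow KO libraries, crossed the KO numbers in the block, blocked WT alone, or compared genotypes within each CPM table. The last held 1 numbered series per genotype and fitted time and genotype, so the times served as replicates. The pairing check used deviations from group means: same-numbered WT libraries correlated across genes at 0.26 to 0.52 in 21 of 21 pairs of times, KO at 72, 96 and 120 h at 0.51 to 0.57 (3 of 3 over 0.1), other KO pairs at -0.14 to 0.18 (4 of 18) and WT with KO at -0.21 to 0.11 (2 of 49 over 0.1), so the numbers pair the WT libraries and the KO libraries of these 3 times, where 1 library per group is shallow, from the values and not the labels.

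The tests were tested on simulated counts for 17519 genes. Each library was drawn independently around a common mean per gene, and only genes of higher counts were changed. Libraries that vary together, as the same-numbered WT libraries did, were not simulated. The rates and false calls that follow therefore do not cover this dependence. For the mean comparison, 68.7%, 91% and 100% of genes changed 1.5-, 2- and 4-fold were called, with 6 false calls. For KO vs WT at 120 h these were 3%, 32.8% and 86.4% with 4 false calls, and at 12 h 0%, 23.9% and 75.8% with 4 false calls. A simulated list of 30 genes raised 1.5-fold was found by camera (limma) in the mean comparison, at an unadjusted p under 0.05. Of 200 unchanged lists, 8 had an unadjusted camera p under 0.05. Genes were also drawn independently, so lists of correlated genes were not covered. Figures were drawn with matplotlib 3.10.9 in Python 3.11.15.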

Results

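Gene expression was measured by polyA RNA sequencing in germ cells sorted from WT and Stra8 KO testes at 0, 12, 18, 48, 72, 96 and 120 h after retinoic acid, with 2 libraries per group and 28 in all. The series asks how spermatogonia move from a synchronised start towards meiosis, and what this course is like without Stra8. Total counts were 5752475 to 10135820 per WT library and 913055 to 9507928 per KO library, with 16820 to 24005 genes detected. Both libraries of a group correlated at 0.959 to 0.98 across genes, except at 0.909, 0.905 and 0.917 in KO at 72, 96 and 120 h, where 1 library was shallow (1078460, 913055 and 1030025 reads). The CPM tables held other values for these 3 libraries, and which set is right was not given in the sources used here. Mitochondrial genes took 1.99 to 3.06% of reads in the 7 WT libraries of the first count table and 3.21 to 8.56% in the other 21 libraries. Replicate numbers below are those of the count tables.

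Stra8, which encodes a factor that germ cells need to enter meiosis (ENSMUSG00000029848.11, chromosome 6, 34920163 to 34939344, + strand, GRCm38), was lower in every KO library than in both WT libraries of its time. The pair of WT libraries held 7.66 and 15.4 CPM at 0 h, 713 and 1043 at 12 h, 746 and 836 at 18 h, 97.2 and 200 at 48 h, 66.6 and 57.4 at 72 h, 41.0 and 57.4 at 96 h, and 17.4 and 30.02 at 120 h. The pair of KO libraries held 0.95 and 1.71 CPM at 0 h, 30.7 and 25.9 at 12 h, 16.3 and 21.5 at 18 h, 62.2 and 2.10 at 48 h, 0.94 and 1.85 at 72 h, and 1.07 and 5.48 at 96 h. At 120 h, KO replicate 1 held 1.66 CPM and replicate 2 had 0 reads, which allows up to 2.91 CPM for counting error only. The KO 48 h library of the first count table had 417 Stra8 reads and its partner 7. Which part of the gene the knockout lacks was not given in the sources used here, so these reads check the labels only in part. Over the 7 times Stra8 was lower in KO by a log2 fold change of -4.35 ± 0.39 (SE; 14 libraries per genotype; edgeR's quasi-likelihood test, Benjamini-Hochberg adjusted p = 1.24e-06). The 14 libraries are not all independent, since same-numbered WT libraries varied together. Against WT of the same time, Stra8 passed at 12 h (-4.95 ± 0.87), 18 h (-5.32 ± 0.89), 72 h (-5.82 ± 1.27), 96 h and 120 h (-4.17 ± 1.24), and did not pass at 0 h (-3.24 ± 1.13) or 48 h (-2.13 ± 0.77).

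**Figure D1:**
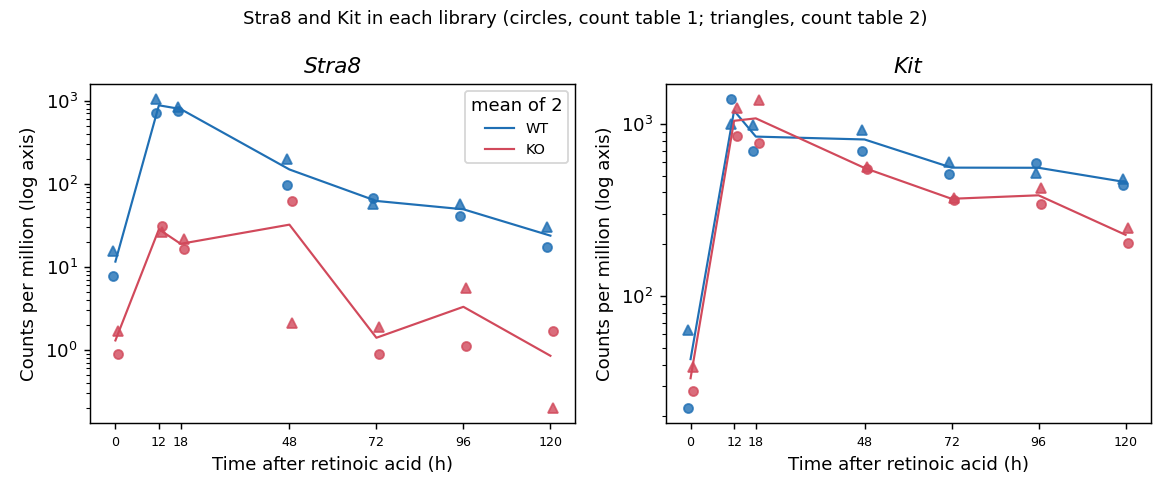
Stra8 and Kit in every library (CPM, log axis) against hours after retinoic acid, by genotype and count table, with values under 0.2 drawn at 0.2. Each KO library lies below both WT libraries of its time for Stra8, while Kit lies above 200 CPM in both genotypes from 12 h on.

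The first question was how WT cells change after retinoic acid. At 12 h Foxn4, a forkhead transcription factor, rose from 0.42 ± 0.117 to 64.4 ± 1.77 CPM (SD, n = 2 per group, as for the later CPM values; log2 fold change 7.24 ± 0.80, SE, as for the later signed values), Cyp26a1, which degrades retinoic acid, by 6.98 ± 0.77 and the receptor gene Rarb by 6.17 ± 0.83. Stra8 rose by 6.27 ± 0.93 and Kit, the receptor of differentiating spermatogonia, from 43.6 ± 30.6 to 1206 ± 292 CPM. Falling genes included Esr1, the oestrogen receptor, from 26.1 ± 7.05 to 1.35 ± 0.06 CPM, the keratin gene Krt75 (log2 -6.10 ± 1.01), Havcr1 (-5.99 ± 0.83), and Il20ra, which had 6.05 ± 1.92 CPM at 0 h and 0 reads in both 12 h libraries. In all 939 genes rose and 968 fell. Of 27 genes of undifferentiated spermatogonia, 1 rose, 18 fell and 8 did not pass (1 and 19 adjusted over the list alone; camera adjusted p = 2.33e-15, and 0.0303 with an estimated correlation). The FGF-pathway phosphatase gene Dusp6 changed by -2.76 ± 0.30, Egr4 by -2.29 ± 0.27 and Upp1 by -2.07 ± 0.26. DNA replication genes rose, 25 of 42 with 0 falling and 17 not passing (36 and 0 adjusted over the list alone; camera adjusted p = 8.79e-21, and 0.0144 with an estimated correlation). The polymerase subunit gene Pola2 (1.39 ± 0.17), Cdc45 (1.46 ± 0.19) and Cdc6 (1.63 ± 0.22) were among these. Of 45 meiotic prophase genes 6 rose, 0 fell and 39 did not pass (7 and 0 adjusted over the list alone; camera adjusted p = 0.00199, but adjusted p = 0.487 with an estimated correlation). Mei1 (1.59 ± 0.22) and the recombinase gene Dmc1 (1.38 ± 0.26) were among these. Of 21 genes of retinoic acid signalling and metabolism, 8 rose, 1 fell and 12 did not pass (9 and 3 adjusted over the list alone; camera adjusted p = 0.00663, but adjusted p = 0.112 with an estimated correlation). The count of 1907 genes became 838 without the WT 0 h replicate 1, 1055 and 1050 without either 12 h library, and 1339 without the other 0 h library. Rarb shares 34.1% of its exon length with Top2b.

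At 18 h, Foxn4 (6.89 ± 0.80), Cyp26a1 (6.19 ± 0.77), Rarb (5.51 ± 0.83) and Stra8 (6.08 ± 0.92) stayed above their 0 h levels in WT. Nr2e1, an orphan nuclear receptor gene of stem cells, fell from 45.1 ± 9.65 to 0.67 ± 0.44 CPM, and Havcr1 (-7.03 ± 0.90) and Gbp2 (-5.15 ± 0.78) fell. Lin28a, an RNA-binding regulator of undifferentiated cells, fell to 111 ± 8.46 CPM (log2 -1.80 ± 0.18) and Nanos3 from 38.7 ± 6.17 to 3.74 ± 1.23 CPM. They were among 18 of 27 undifferentiated genes that fell, with 0 rising and 9 not passing (0 higher and 20 lower adjusted over the list alone; camera adjusted p = 8.64e-18, and 0.0342 with an estimated correlation). Of 16 genes of differentiating spermatogonia, 4 rose, 1 fell and 11 did not pass (5 and 1 adjusted over the list alone; camera adjusted p = 0.0278, but adjusted p = 0.329 with an estimated correlation). Kit changed by 4.25 ± 0.40, Ccnd2 by 2.00 ± 0.24 and Sohlh2 by 1.13 ± 0.20. Of 24 immediate early genes 6 fell, 0 rose and 18 did not pass (1 higher and 6 lower adjusted over the list alone; camera adjusted p = 0.0426, but 0.329 with an estimated correlation). Egr1 (-2.05 ± 0.31) and Hspa1a (-2.19 ± 0.52) were among these. The camera call of the immediate early list was also lost with the replicate number as a block. In all 889 genes rose and 1204 fell, a count of 2093 that became 870 without the 0 h replicate 1, 1533 without the other 0 h library, 1181 without the 18 h replicate 1 and 933 without its partner.

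WT cells at 48 h were marked by Id2, an inhibitor of helix-loop-helix factors, which rose from 0.14 ± 0.04 to 5.82 ± 1.29 CPM (log2 5.24 ± 0.76), and by Plk5 (4.46 ± 0.52) and Tbx1 (3.89 ± 0.51). Onecut2, a homeobox factor gene, fell from 141 ± 58.8 to 11.5 ± 5.03 CPM and the syntrophin gene Sntg2 by 3.90 ± 0.41 on the log2 scale. Trpv5 had 5.10 ± 3.90 CPM at 0 h and 0 reads in both 48 h libraries. Of 27 undifferentiated genes 12 fell, 0 rose and 15 did not pass (0 higher and 15 lower adjusted over the list alone; camera adjusted p = 4.03e-08, but adjusted p = 0.158 with an estimated correlation). Upp1 changed by -3.11 ± 0.27 and Pou5f1, the pluripotency factor gene, by -2.98 ± 0.31. Of 36 mitosis genes 12 rose, 0 fell and 24 did not pass (17 and 0 adjusted over the list alone; camera adjusted p = 8.70e-08, but 0.432 with an estimated correlation). Top2a (1.31 ± 0.20) and Prc1 (1.36 ± 0.21) were among these. In the piRNA and germline list 2 of 25 genes rose, 5 fell and 18 did not pass (3 and 8 adjusted over the list alone; camera adjusted p = 0.0481, but 0.432 with an estimated correlation). Piwil4 fell by 1.73 ± 0.27 and Tdrd5 by 1.28 ± 0.21. The Sertoli marker Cldn11 rose (3.26 ± 0.91), the only 1 of 18 Sertoli markers that passed (1 and 0 adjusted over the list alone; camera adjusted p = 0.00922, but 0.587 with an estimated correlation). Stra8 was still up by 3.69 ± 0.84, a call lost without the 0 h replicate 1 or the 48 h replicate 2 (edgeR's quasi-likelihood test, Benjamini-Hochberg adjusted p up to 0.142). The count of 2249 genes (1078 higher, 1171 lower) became 753 and 1603 without the 0 h replicates 1 and 2, and 1372 and 756 without the 48 h replicates 1 and 2.

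At 72 h in WT, Dmrtb1, a DM-domain factor gene of the passage from mitosis to meiosis, rose from 9.14 ± 9.12 to 76.3 ± 2.42 CPM (log2 3.12 ± 0.59), and Plk5 (3.96 ± 0.52), Paqr5 (4.21 ± 0.78) and Kit (3.72 ± 0.39) were up. The tubulin gene Tubb2b (-3.47 ± 0.60), Cebpb (-3.88 ± 0.75) and the carboxypeptidase gene Cpz (-4.12 ± 0.51) fell. Stra8 did not pass at 72 h (2.48 ± 0.81), 96 h or 120 h, and passed at these times with WT alone and the replicate number as a block, a choice made after the data were examined (edgeR's quasi-likelihood test, Benjamini-Hochberg). Of 16 differentiating genes 7 rose, 2 fell and 7 did not pass (8 and 3 adjusted over the list alone; camera adjusted p = 0.00308, but adjusted p = 0.223 with an estimated correlation). Esx1 (1.91 ± 0.37) and Dnmt3b (0.80 ± 0.17) were among these. In DNA replication 21 of 42 genes rose, 0 fell and 21 did not pass (26 and 3 adjusted over the list alone; camera adjusted p = 1.50e-10, but 0.0902 with an estimated correlation). Ccne1 (1.60 ± 0.22) and Rrm2 (1.86 ± 0.28) were among these. Among glycolysis genes, 1 of 18 rose, 4 fell and 13 did not pass (1 and 4 adjusted over the list alone; camera adjusted p = 0.0131, but 0.783 with an estimated correlation). Hk1 (-1.05 ± 0.21) and Pfkm (-0.96 ± 0.21) fell and Hk2 (0.83 ± 0.24) rose. In all 1147 genes rose and 1109 fell, and the count of 2256 became 537 and 1645 without the 0 h replicates 1 and 2, and 1147 and 1563 without the 72 h replicates 1 and 2.

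By 96 h Dmrtb1 had reached 220 ± 72.9 CPM in WT (log2 4.65 ± 0.62), and Pkp1, which encodes a desmosome protein, Fgf3 and Tbx1 were up by 5.32 ± 0.91, 4.56 ± 0.87 and 4.42 ± 0.51. Adcy2, an adenylyl cyclase gene, fell by 5.21 ± 0.77 on the log2 scale, Tmprss5 by 4.04 ± 0.47 and the sorting receptor gene Sorcs3 by 3.49 ± 0.45. In all 2209 genes rose and 2467 fell. Mitosis genes rose, 22 of 36 with 0 falling and 14 not passing (24 and 0 adjusted over the list alone; camera adjusted p = 8.36e-10, but adjusted p = 0.316 with an estimated correlation). The kinase gene Plk1 changed by 2.74 ± 0.38 and Tpx2 by 1.70 ± 0.25. In the piRNA and germline list 1 of 25 genes rose, 15 fell and 9 did not pass (1 and 16 adjusted over the list alone; camera adjusted p = 2.07e-04, but 0.157 with an estimated correlation). Piwil4 (-1.98 ± 0.27), Dnmt3l (-2.58 ± 0.50) and Gtsf1 (-1.37 ± 0.27) were among these. Of 27 undifferentiated genes 18 fell, 0 rose and 9 did not pass (0 higher and 19 lower adjusted over the list alone; camera adjusted p = 8.36e-10, but 0.145 with an estimated correlation). The count of 4676 became 2409 without the 0 h replicate 1 and 3029 without the 96 h replicate 2, and stayed within 1.5 times without either of the others (3595 and 4171).

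In WT at 120 h, Prdm9, which places recombination sites, rose from 3.98 ± 1.02 to 45.1 ± 12.3 CPM (log2 3.51 ± 0.45), Ythdc2, needed for the exit from mitosis, from 45.0 ± 0.61 to 160 ± 8.82 CPM, and Mei1 by 1.86 ± 0.22. They were among 15 of 45 meiotic prophase genes that rose, with 6 falling and 24 not passing (16 and 6 adjusted over the list alone; camera adjusted p = 0.0192, but adjusted p = 0.41 with an estimated correlation). Esx1, an X-linked homeobox gene, reached 303 ± 128 from 11.3 ± 1.58 CPM, the testis protease gene Prss50 rose by 5.09 ± 0.67, Otud6a by 5.58 ± 0.76 and St6galnac2 by 5.77 ± 0.62. Hoxb3 (-3.09 ± 0.55), Chst5 (-3.86 ± 0.70) and Ephx2 (-2.91 ± 0.38) fell. Of 36 mitosis genes 27 rose, 0 fell and 9 did not pass (27 and 0 adjusted over the list alone; camera adjusted p = 6.56e-12, but 0.278 with an estimated correlation). Top2a stood at 1103 ± 90.0 against 312 ± 92.9 CPM. Of 42 replication genes 30 rose, 2 fell and 10 did not pass (32 and 2 adjusted over the list alone; camera adjusted p = 6.77e-12, but 0.07 with an estimated correlation). E2f2 changed by 4.16 ± 0.48. Glycolysis genes fell, 9 of 18 with 0 rising and 9 not passing (0 higher and 10 lower adjusted over the list alone; camera adjusted p = 7.63e-04, but 0.329 with an estimated correlation). Pfkp (-1.66 ± 0.24) and Pfkm (-1.25 ± 0.21) were among these. Of 27 undifferentiated genes 21 fell, 0 rose and 6 did not pass (0 higher and 23 lower adjusted over the list alone; camera adjusted p = 1.08e-11, but 0.07 with an estimated correlation). In all 2485 genes rose and 2573 fell. The count of 5058 became 2686 without the 0 h replicate 1 and 2571 without the 120 h replicate 2, and 4073 and 4452 without the others. Over the whole WT time course 6534 genes changed at any time (5126 to 7225 with 1 library left out).

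**Figure D2:**
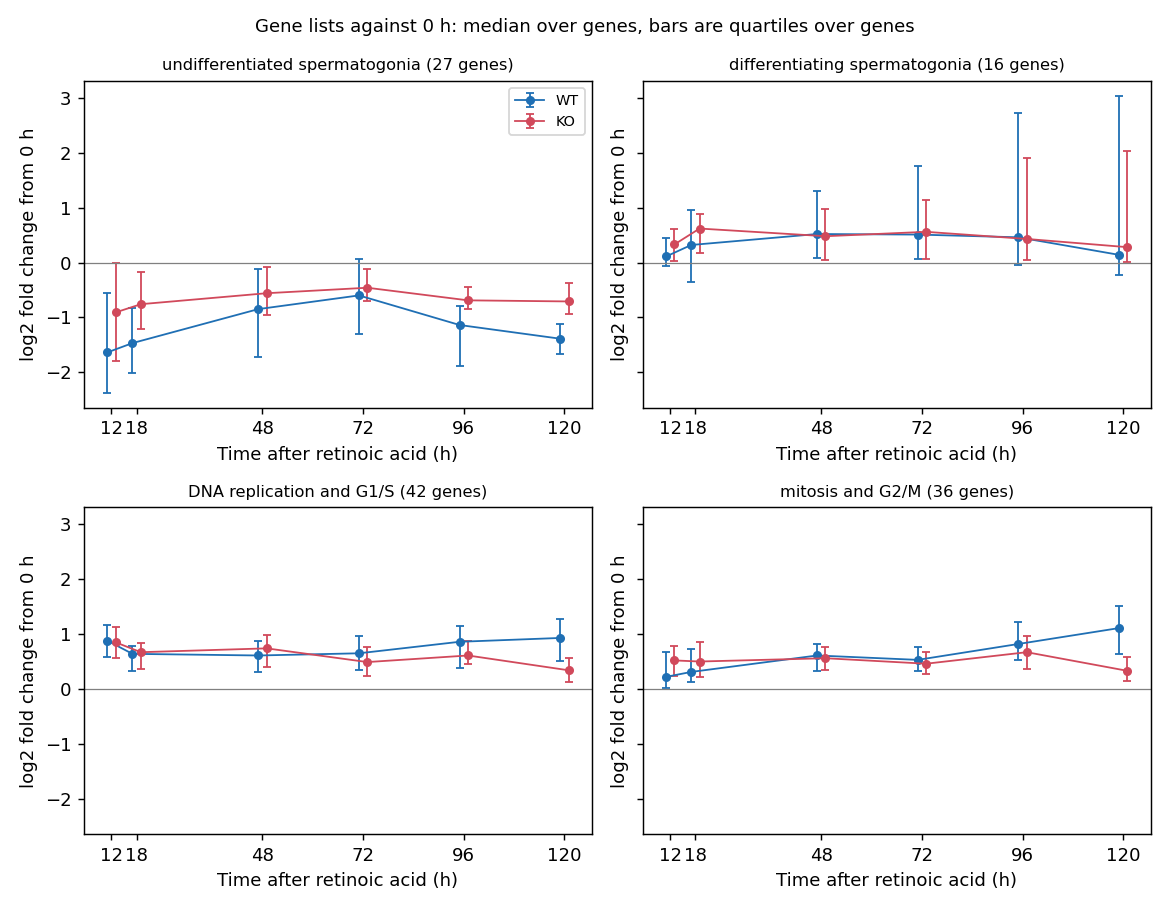
Median log2 fold change from 0 h of genes in each list (points) with quartiles (bars) against hours, for WT and KO. The median of the undifferentiated list in WT lies at -1.64 at 12 h and -1.39 at 120 h.

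The next question was which of these changes KO cells made. At 12 h KO cells raised the same receptor and enzyme genes: Kit rose from 32.7 ± 6.81 to 1048 ± 273 CPM, Cyp26a1 by 5.50 ± 0.69, Rarb by 4.40 ± 0.75 and Ccnd2 by 2.99 ± 0.25. L1td1, an RNA-binding protein gene of pluripotent cells, rose from 0.41 ± 0.43 to 27.3 ± 2.68 CPM, Sstr2 by 6.84 ± 0.98 and the retinol-oxidising Adh1 by 6.30 ± 0.88, while Nr2e1 (-3.86 ± 0.50), Sox10 (-3.70 ± 0.51) and Eya1 (-4.58 ± 0.84) fell. In all 724 genes rose and 778 fell. Replication genes rose, 28 of 42 with 0 falling and 14 not passing (32 and 0 adjusted over the list alone; camera adjusted p = 3.50e-20, and 0.0213 with an estimated correlation). Lig1 (1.09 ± 0.17) was among these. Of 27 undifferentiated genes 12 fell, 0 rose and 15 did not pass (2 higher and 13 lower adjusted over the list alone; camera adjusted p = 3.31e-07, but adjusted p = 0.215 with an estimated correlation). Dusp6 changed by -2.16 ± 0.30 and Spry4 by -3.48 ± 0.51. Of 45 meiotic prophase genes 6 rose, 0 fell and 39 did not pass (7 and 0 adjusted over the list alone; camera adjusted p = 8.32e-05, but 0.281 with an estimated correlation). The cohesin gene Rec8 (1.33 ± 0.33) was among these. The Stra8 reads left in KO also rose, by 4.56 ± 1.09, a call lost without any 1 of the 4 libraries (edgeR's quasi-likelihood test, Benjamini-Hochberg adjusted p up to 0.266). The count of 1502 became 346 and 944 without the KO 0 h replicates 1 and 2, and 507 and 549 without the 12 h replicates 1 and 2.

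In KO at 18 h, Kit stood at 1107 ± 423 CPM (log2 5.09 ± 0.42), and L1td1 was up by 5.89 ± 0.79 and Stra6, a receptor gene of retinol uptake, by 3.62 ± 0.63. Nr2e1 (-3.90 ± 0.50) and the ETS factor gene Fli1 (-3.79 ± 0.63) were down, and 668 genes rose and 896 fell. Of 27 undifferentiated genes 11 fell, 0 rose and 16 did not pass (0 higher and 14 lower adjusted over the list alone; camera adjusted p = 3.68e-07, but adjusted p = 0.186 with an estimated correlation). Nanos3 changed by -1.95 ± 0.31, Upp1 by -1.48 ± 0.25 and Zbtb16, a self-renewal factor gene, by -1.11 ± 0.26. At 48 h Kit (4.11 ± 0.40) and the phospholipase gene Plch2 (3.64 ± 0.44) were up in KO, and 310 genes rose and 480 fell. Of 42 replication genes 17 rose, 0 fell and 25 did not pass at 48 h (26 and 0 adjusted over the list alone; camera adjusted p = 8.03e-18, and 0.0351 with an estimated correlation). Mcm2 changed by 0.99 ± 0.17 and Fen1 by 0.99 ± 0.18. The 18 h count of 1564 became 251 and 973 without the 0 h replicates 1 and 2, and 433 and 503 without the 18 h replicates 1 and 2, and the 48 h count of 790 became 69, 430, 35 and 264 in the same order. Stra8 in KO at 48 h was up by 4.80 ± 1.09, which became 0.81 without the 48 h replicate 1, and its call was lost without that library or either 0 h library (edgeR's quasi-likelihood test, Benjamini-Hochberg adjusted p up to 0.886).

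In KO at 72 h, Kit (3.48 ± 0.39), Plch2 (3.51 ± 0.45) and Dmrtb1, at 79.2 ± 2.48 against 4.30 ± 0.30 CPM, were up, and the stress gene Ddit4 was down (-1.90 ± 0.27). At 96 h Dmrtb1 stood at 125 ± 40.7 CPM and Esx1 at 120 ± 47.7 CPM. At 120 h Otud6a (5.62 ± 0.93), Prss50 (4.10 ± 0.68), Prdm9 (2.05 ± 0.48) and E2f2 (2.81 ± 0.47) were up and Dusp6 (-1.84 ± 0.32) was down. In all 61 genes rose and 25 fell at 72 h, 223 and 84 at 96 h, and 159 and 8 at 120 h. These were 70.9, 72.6 and 95.2% higher, against 59.0% at 96 h with DESeq2. With limma and the CPM table number as block, 50.8, 52.8 and 81.3% were higher on log2 CPM + 1. On CPM + 0.1 the shares were 53.5, 57.3 and 81.5%. The limma fits used the deposited CPM, which hold other values for the 3 shallow libraries, so method and input both changed. Of 16 differentiating genes 6 rose, 0 fell and 10 did not pass at 96 h (7 and 0 adjusted over the list alone; camera adjusted p = 2.26e-06, and 0.0365 with an estimated correlation). In replication 7 of 42 genes rose at 96 h, 0 fell and 35 did not pass (26 and 0 adjusted over the list alone; camera adjusted p = 3.19e-14, and 0.0365 with an estimated correlation). Among 27 undifferentiated genes 2 fell at 72 h, 0 at 96 h and 1 at 120 h, with 0 rising at each time (lower genes adjusted over the list alone, 8, 0 and 4; camera adjusted p = 1.56e-05, 5.19e-07 and 1.11e-08, but adjusted p = 0.333, 0.218 and 0.134 with an estimated correlation). None of 18 Sertoli markers passed at 72 h, and 8 rose adjusted over the list alone (median 1.90; camera adjusted p = 1.09e-07, but 0.333 with an estimated correlation). Clu stood at 158 CPM in replicate 1 and 632 CPM in replicate 2. Without the 3 shallow libraries the counts were 7, 20 and 52 in place of 86, 307 and 167, and with recovered reads in their place 277, 757 and 235. The counts at 72, 96 and 120 h also became 8, 23 and 9 without the 0 h replicate 1, 6, 17 and 16 without the 0 h replicate 2, 79, 222 and 66 without replicate 1 of the later time, and 10, 24 and 48 without its replicate 2. Dmrtb1 lost its call at 72, 96 and 120 h without either 0 h library, and at 72 h without the shallow one (edgeR's quasi-likelihood test, Benjamini-Hochberg adjusted p up to 0.24, 0.0886 and 0.113). At 120 h Otud6a lost its call without the 0 h replicate 1, Prss50 without either 0 h library, and Dusp6 without the 0 h replicate 1 or either 120 h library (edgeR's quasi-likelihood test, Benjamini-Hochberg adjusted p up to 0.16, 0.132 and 0.076). Prdm9 and E2f2 were not tested in this way. Over the KO time course 2763 genes changed at any time, and 1819 without the shallow libraries.

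WT and KO responses to retinoic acid shared no library and could be set side by side. Log2 fold changes from 0 h correlated across 17519 genes between the genotypes with Pearson's r of 0.56, 0.50, 0.52, 0.41, 0.50 and 0.41 from 12 to 120 h, and Spearman's rho of 0.53, 0.48, 0.51, 0.50, 0.56 and 0.52 (genes are not independent replicates). At 12 h 448 genes rose in both, against 38.8 for independent lists, and 443 fell in both, against 43. At this time 0 went opposite ways, and at 18 h 6 did. At 120 h 155 rose in both, against 22.6, and 4 fell in both, against 1.2. Of the genes called in WT, 96.3% at 12 h, 91.2% at 18 h and 92.6% at 120 h had the same sign in KO.

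**Figure D3:**
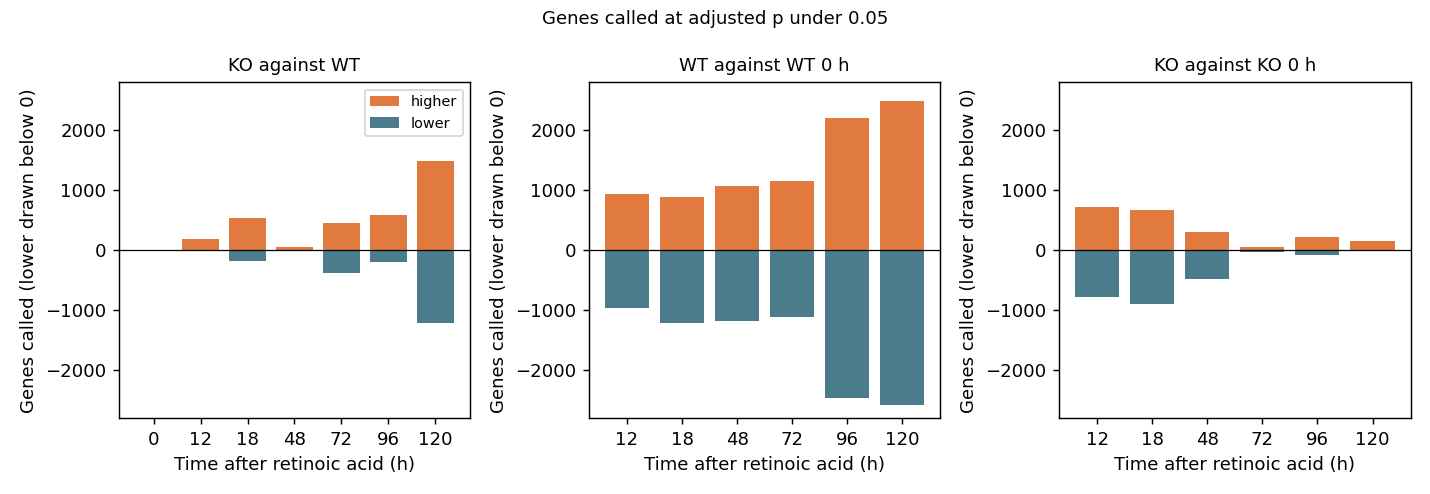
Genes called higher and lower in each comparison (bars from 0). WT against 0 h gave 1907 genes at 12 h and 5058 at 120 h, and KO against 0 h gave 1502 and 167.

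The main question was how KO cells differ from WT cells. Over the 7 times, 3051 genes were higher and 3517 lower in KO (14 libraries per genotype). These 14 form 2 numbered series, and the same-numbered WT libraries varied together over the times. They are thus not 14 independent replicates, and the SEs and p-values of this comparison may be too small. Splits of the series that mixed the genotypes called 440 and 1 genes. Igfbp6, which binds insulin-like growth factors, stood at 30.3 ± 12.0 in KO and 9.94 ± 10.6 CPM in WT (log2 2.09 ± 0.15), Mobp at 29.3 ± 8.08 and 9.42 ± 8.98 CPM, the ubiquitin ligase gene Dtx1 at 42.6 ± 24.9 and 12.1 ± 13.0 CPM, and Krt75 was higher by 3.44 ± 0.29. The stress-response factor gene Cebpb was higher by 2.27 ± 0.25, with 20.7% of its exon length shared with Tmem189. Lower genes included Scube2, a secreted signalling cofactor gene (-1.66 ± 0.17), and Sec14l2 (-1.58 ± 0.17). Lars2 and Yam1 were also lower (-3.66 ± 0.83 and -1.79 ± 0.51), but these followed 1 set of libraries. Lars2 held 7666 ± 1896 CPM in WT and 432 ± 265 in KO of the first count table, and 400 ± 161 in WT and 234 ± 112 in KO of the second (7 libraries each). Between WT of the second count table and KO of the first, which share a CPM table, Lars2 and Yam1 were higher in KO by 0.06 and 0.37, neither past the threshold. There 1543 genes differed, 70.1% of them higher in KO, against 46.5% of the 6568 over all libraries, and 4445 differed within the other CPM table. Each of these fits held 1 numbered series per genotype, with the 7 times as replicates. Genotype and series cannot be told apart in them, and their p-values may be too small.

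Markers of undifferentiated spermatogonia were higher in KO over the 7 times: Egr4 at 94.95 ± 29.1 in KO and 37.2 ± 34.7 CPM in WT (log2 1.65 ± 0.10), the chromatin factor gene Utf1 at 22.9 ± 6.57 and 7.58 ± 5.97 CPM, Upp1 at 80.9 ± 40.2 and 33.2 ± 33.8 CPM, and Lin28a at 346 ± 71.3 and 200 ± 89.7 CPM. Of 27 such genes 16 were higher, 0 lower and 11 did not pass (17 and 0 adjusted over the list alone; camera adjusted p = 5.26e-07, but adjusted p = 0.323 with an estimated correlation). In meiotic prophase 18 of 45 genes were lower, 3 higher and 24 did not pass (3 higher and 18 lower adjusted over the list alone; camera adjusted p = 0.00701, but 0.383 with an estimated correlation). Ythdc2 (-0.68 ± 0.09), the cohesin gene Smc1b (-0.63 ± 0.09) and Prdm9 (-1.18 ± 0.17) were among these. Of 42 replication genes 21 were lower, 1 higher and 20 did not pass (1 higher and 25 lower adjusted over the list alone; camera adjusted p = 7.17e-04, but 0.342 with an estimated correlation). Rrm2 stood at 24.9 ± 8.04 in KO and 47.4 ± 27.5 CPM in WT, and Chaf1b, a histone chaperone gene, was the 1 higher (1.16 ± 0.09). Of 36 mitosis genes 17 were lower, 1 higher and 18 did not pass (1 higher and 18 lower adjusted over the list alone; camera adjusted p = 4.57e-04, but 0.452 with an estimated correlation). Prc1 (-0.58 ± 0.08), Anln (-0.48 ± 0.07) and Bub1 (-0.62 ± 0.10) were among these.

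Glycolysis genes were higher in KO, 12 of 18 with 1 lower and 5 not passing (13 and 1 adjusted over the list alone; camera adjusted p = 0.00129, but adjusted p = 0.383 with an estimated correlation). Pfkm changed by 0.60 ± 0.08, Tpi1 by 0.82 ± 0.13 and Ldhb by 0.92 ± 0.15. In the retinoic acid list 9 of 21 genes were higher, 1 lower and 11 did not pass (9 and 1 adjusted over the list alone; camera adjusted p = 0.0391, but 0.323 with an estimated correlation). The receptor gene Rarg (0.70 ± 0.07) and Stra6 (1.47 ± 0.29) were among these. Of 24 immediate early genes 10 were higher, 0 lower and 14 did not pass (10 and 0 adjusted over the list alone; camera adjusted p = 0.00104, but 0.323 with an estimated correlation). Egr1 (0.78 ± 0.12) and Nr4a1 (0.51 ± 0.09) were among these. Differentiating genes split, 7 of 16 higher, 5 lower and 4 not passing (7 and 6 adjusted over the list alone; camera adjusted p = 0.727, with an upward test and a median of -0.12). Sohlh1 (0.64 ± 0.08) and Dmrt1 (0.38 ± 0.08) were higher, and Prss50 (-1.31 ± 0.27) and Dnmt3b (-0.26 ± 0.06) lower. In the piRNA and germline list 11 of 25 genes were higher, 4 lower and 10 did not pass (11 and 5 adjusted over the list alone; camera adjusted p = 0.0679). Dnmt3l changed by 1.76 ± 0.18 and Tex19.1 by 0.50 ± 0.07.

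Somatic markers were measured beside these. Of 18 Sertoli markers 8 were higher in KO, 0 lower and 10 did not pass (8 and 0 adjusted over the list alone; camera adjusted p = 0.00112, but adjusted p = 0.383 with an estimated correlation). Wt1 stood at 19.0 ± 8.82 in KO and 9.91 ± 3.69 CPM in WT and Gata4 at 11.8 ± 3.17 and 8.38 ± 3.10 CPM. Of 14 myoid and stromal markers 5 were higher, 0 lower and 9 did not pass (5 and 0 adjusted over the list alone; camera adjusted p = 0.00895, but 0.342 with an estimated correlation). The collagen gene Col1a1 stood at 198 ± 102 and 102 ± 68.2 CPM and Dlk1 at 188 ± 67.1 and 87.4 ± 43.9 CPM. Of 8 endothelial markers 2 were higher (Vwf 1.06 ± 0.21 and Pecam1 0.64 ± 0.17; 2 adjusted over the list alone; camera adjusted p = 0.53, with an upward test and a median of -0.01). Among 5 spermatid markers 1 was higher, Hspa1l (1.23 ± 0.21; 1 adjusted over the list alone; camera adjusted p = 0.0825). None of 5 Leydig, 5 leukocyte and 2 erythroid markers passed (0 adjusted over the list alone; camera adjusted p = 0.53, 0.828 and 0.505).

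At 0 h, before retinoic acid, 0 genes differed between KO and WT (edgeR's quasi-likelihood test, Benjamini-Hochberg), with 1193 at an unadjusted p under 0.05, where 876 would be expected by chance. DESeq2 and limma also called 0, the fit without a filter 73 and the fit with the replicate block 1. The smallest p-values belonged to Tlr12, a Toll-like receptor gene (3.86 ± 0.88), Foxn4 (3.92 ± 0.87) and Tesk1 (0.80 ± 0.20; 32.1% of its exon length is shared with Cd72), and none of the 3 passed (edgeR's quasi-likelihood test, Benjamini-Hochberg adjusted p = 0.71). Meiotic prophase genes lay lower as a list, with 0 of 45 passing (0 adjusted over the list alone; median -0.34; camera adjusted p = 0.00131, but adjusted p = 0.903 with an estimated correlation). Hormad2 stood at 12.6 ± 0.39 in KO and 20.3 ± 0.98 CPM in WT. Sertoli markers lay higher, with 0 of 18 passing (0 adjusted over the list alone; camera adjusted p = 0.0208, but 0.903 with an estimated correlation). Of these, Cldn11 held 8.6 and 1.2 CPM in KO replicates 1 and 2 against 0.7 and 2 CPM in WT, Inha 10.6 and 2.4 against 2.7 and 5.2, and Clu 103 and 39.7 against 22.3 and 32.9, each highest in KO replicate 1.

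At 12 h Krt75 stood at 5.45 ± 1.45 in KO and 0.05 ± 0.07 CPM in WT (log2 6.13 ± 1.02), the receptor ligand gene Pdcd1lg2 at 9.38 ± 3.53 and 0.60 ± 0.42 CPM, Neurog3, a progenitor factor gene, at 29.4 ± 2.58 and 7.15 ± 0.06 CPM, and Lin28a at 434 ± 42.3 and 234 ± 15.3 CPM. The dynein gene Dnah10 was lower (7.38 ± 0.89 and 27.3 ± 4.95 CPM; log2 -1.90 ± 0.35). In all 190 genes were higher and 17 lower (91.8% higher). With limma and the CPM table number as block, 79.5% were higher on log2 CPM + 1 and 76.2% on CPM + 0.1. Among 27 undifferentiated genes 5 were higher, 0 lower and 22 did not pass (8 and 0 adjusted over the list alone; camera adjusted p = 1.98e-07, but adjusted p = 0.229 with an estimated correlation). Of 21 retinoic acid genes 1, Rarg (0.87 ± 0.18), was higher and 0 were lower (1 and 0 adjusted over the list alone; camera adjusted p = 0.0219, but 0.229 with an estimated correlation), and 0 of 45 meiotic prophase genes passed (0 adjusted over the list alone; camera adjusted p = 0.0219 for lower, but 0.759 with an estimated correlation). The count of 207 became 60 and 19 without the WT 12 h replicates 1 and 2, and 64 without either KO 12 h library. Calls were lost for Krt75 without WT replicate 2, for Pdcd1lg2 without WT replicate 1 or 2 or KO replicate 2, for Dnah10 without WT replicate 1 or either KO library and for Stra8 without WT replicate 2 or either KO library (edgeR's quasi-likelihood test, Benjamini-Hochberg adjusted p up to 0.0742, 0.18, 0.172 and 0.182).

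At 18 h Lin28a stood at 322 ± 4.94 in KO and 111 ± 8.46 CPM in WT (log2 1.53 ± 0.18), Upp1 at 52.6 ± 8.15 and 14.8 ± 2.60 CPM, and Pdcd1lg2 (6.58 ± 0.99), the carboxypeptidase-like gene Cpxm2 (5.02 ± 0.62) and Dmkn (4.84 ± 0.54) were higher. Lower were Dnah10, at 6.42 ± 0.53 and 41.9 ± 11.1 CPM (log2 -2.70 ± 0.36), and Lynx1 (-2.68 ± 0.45). In all 544 genes were higher and 182 lower (74.9% higher). With limma and the CPM table number as block, 56.7% were higher on log2 CPM + 1 and 55.2% on CPM + 0.1. Among 27 undifferentiated genes 8 were higher, 0 lower and 19 did not pass (13 and 0 adjusted over the list alone; camera adjusted p = 9.25e-11, but adjusted p = 0.181 with an estimated correlation), and of 18 glycolysis genes 1, Ldhb (2.35 ± 0.39), was higher and 0 were lower (2 and 0 adjusted over the list alone; camera adjusted p = 0.00218, but 0.467 with an estimated correlation). Of 14 myoid and stromal markers 2 were higher, Igfbp5 (1.75 ± 0.42) and Des (1.99 ± 0.48), and 0 lower (5 and 0 adjusted over the list alone; camera adjusted p = 3.88e-04, but 0.205 with an estimated correlation). The count of 726 became 176 and 356 without the WT replicates 1 and 2, and 277 and 302 without the KO replicates 1 and 2; Stra8 lost its call without either KO library (edgeR's quasi-likelihood test, Benjamini-Hochberg adjusted p up to 0.0697).

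At 48 h 51 genes were higher and 3 lower in KO (94.4% higher). With limma and the CPM table number as block, 79.6% were higher on log2 CPM + 1 and 81.9% on CPM + 0.1. Upp1 stood at 45.7 ± 7.68 in KO and 12.9 ± 5.13 CPM in WT (log2 1.81 ± 0.27), Egr4 at 92.3 ± 27.9 and 25.9 ± 7.24 CPM, and the RNA-binding Nanos3 at 18.4 ± 6.67 and 5.62 ± 0.27 CPM. Sntg2 (2.43 ± 0.41) and Igfbp6 (2.24 ± 0.40) were also higher, and Scube2 (-1.99 ± 0.42), Tmem9 (-1.34 ± 0.29) and Ankrd13a (-0.83 ± 0.18) lower. Among 27 undifferentiated genes 4 were higher, 0 lower and 23 did not pass (8 and 0 adjusted over the list alone; camera adjusted p = 8.98e-06, but adjusted p = 0.354 with an estimated correlation). Of 36 mitosis genes none passed (0 adjusted over the list alone; camera adjusted p = 0.0256 for lower, but 0.96 with an estimated correlation). The count of 54 became 21 and 2 without the WT replicates 1 and 2, and 23 and 0 without the KO replicates 1 and 2. Sntg2 and Igfbp6 lost their calls without either WT library or KO replicate 2, and Scube2, Tmem9 and Ankrd13a without any 1 library (edgeR's quasi-likelihood test, Benjamini-Hochberg adjusted p up to 0.192, 0.455, 0.814, 0.52 and 0.783).

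At 72 h Pgm5 stood at 23.4 ± 2.60 in KO and 1.93 ± 1.31 CPM in WT (log2 3.63 ± 0.48), the calcium channel gene Itpr2 at 17.7 ± 9.32 and 1.44 ± 0.94 CPM, Utf1 at 20.7 ± 1.27 and 4.10 ± 0.19 CPM, and Pax7, a marker of rare stem-like spermatogonia, at 19.5 ± 1.70 and 3.82 ± 0.20 CPM. The melanocyte factor gene Mitf was lower (-2.24 ± 0.48), as was Ythdc2 (-1.04 ± 0.24). In all 452 genes were higher and 371 lower (54.9% higher; 88.1% without the 3 shallow libraries and 71.9% with an added 2-fold threshold). In the undifferentiated list of 27 genes, 6 were higher, 0 lower and 21 did not pass (7 and 0 adjusted over the list alone; camera adjusted p = 0.0172, but adjusted p = 0.6 with an estimated correlation), and of 45 meiotic prophase genes 3 were lower, 1 higher and 41 did not pass (1 higher and 7 lower adjusted over the list alone; camera adjusted p = 0.0109, but 0.6 with an estimated correlation). None of 18 Sertoli markers passed, and 11 were higher adjusted over the list alone (median 1.62; camera adjusted p = 4.11e-08, but 0.403 with an estimated correlation). Inha held 12.3 CPM in KO replicate 1 and 53.8 in KO replicate 2. The count of 823 became 135 without the 3 shallow libraries, 1414 with recovered reads in their place, 86 without WT replicate 1, 246 without KO replicate 1, 122 without KO replicate 2, 737 without WT replicate 2 and 1 with these groups compared alone. Mitf lost its call without WT replicate 1 or either KO library, as did Stra8 (edgeR's quasi-likelihood test, Benjamini-Hochberg adjusted p up to 0.103 and 0.187).

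At 96 h Upp1 stood at 77.7 ± 33.8 in KO and 18.4 ± 1.12 CPM in WT (log2 2.13 ± 0.27), and Pax7 at 20.1 ± 0.83 and 5.20 ± 0.39 CPM. Sorcs3 (3.14 ± 0.47), the amino acid transporter gene Slc38a4 (2.75 ± 0.37) and Ly6g6e (2.86 ± 0.46; 18% of its exon length is shared with Ly6g6d) were higher, and the synaptic scaffold gene Shank1 (-3.40 ± 0.69), Dok7 (-2.80 ± 0.53) and Fibcd1 (-2.64 ± 0.49) lower. In all 581 genes were higher and 202 lower (74.2% higher; 61.4% with DESeq2). In the undifferentiated list of 27 genes, 9 were higher, 0 lower and 18 did not pass (12 higher and 1 lower adjusted over the list alone; camera adjusted p = 9.19e-08, but adjusted p = 0.472 with an estimated correlation). Of 25 piRNA and germline genes 6 were higher, 0 lower and 19 did not pass (9 and 1 adjusted over the list alone; camera adjusted p = 0.00167, but 0.472 with an estimated correlation). Dnmt3l changed by 2.36 ± 0.52 and Piwil4 by 1.06 ± 0.28. Of 36 mitosis genes 1, Prc1 (-0.75 ± 0.21), was lower and 0 higher (0 higher and 2 lower adjusted over the list alone; camera adjusted p = 4.99e-04, but 0.625 with an estimated correlation). The count of 783 became 30 without KO replicate 1 and 347 without WT replicate 1 (731 and 755 without the others), and 0 with these groups compared alone in edgeR, where 1444 genes had an unadjusted p under 0.05 and DESeq2 with all groups called 1020. Without KO replicate 1, leaving the shallow library as the only KO library, Sorcs3, Slc38a4, Ly6g6e, Shank1, Dok7 and Fibcd1 lost their calls (edgeR's quasi-likelihood test, Benjamini-Hochberg adjusted p up to 0.11, 0.29, 0.175, 0.239, 0.227 and 0.227). Stra8 lost its call without any 1 of the 4 libraries (edgeR's quasi-likelihood test, Benjamini-Hochberg adjusted p up to 0.435).

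At 120 h 1496 genes were higher and 1206 lower in KO. Upp1 stood at 127 ± 23.0 in KO and 23.6 ± 0.21 CPM in WT (log2 2.41 ± 0.26), Lin28a at 322 ± 44.0 and 118 ± 16.2 CPM, Utf1 at 24.9 ± 2.44 and 4.62 ± 0.90 CPM, the neuronal splicing factor gene Rbfox3 at 12.0 ± 1.19 and 0.92 ± 0.58 CPM, and Hoxb3 at 10.2 ± 1.19 and 0.72 ± 0.11 CPM (52.9% of its exon length is shared with Hoxb3os). The homeobox gene Dmbx1 was lower, at 2.33 ± 0.70 and 25.3 ± 8.41 CPM. In the undifferentiated list of 27 genes, 14 were higher, 0 lower and 13 did not pass (14 and 0 adjusted over the list alone; median 0.84; camera adjusted p = 1.32e-06, but adjusted p = 0.251 with an estimated correlation). Mitosis genes were lower, 19 of 36 with 0 higher and 17 not passing (0 higher and 27 lower adjusted over the list alone; median -0.86; camera adjusted p = 2.54e-10, but 0.259 with an estimated correlation). The topoisomerase gene Top2a stood at 445 ± 61.4 and 1103 ± 90.0 CPM, and Prc1 (-1.39 ± 0.21) and Kif11 (-1.35 ± 0.26) were also lower. Of 42 replication genes 19 were lower, 1 higher and 22 did not pass (1 higher and 25 lower adjusted over the list alone; camera adjusted p = 3.83e-08, but 0.251 with an estimated correlation). Rrm2 changed by -1.76 ± 0.29. Of 45 meiotic prophase genes 9 were lower, 0 higher and 36 did not pass (1 higher and 9 lower adjusted over the list alone; camera adjusted p = 4.35e-04, but 0.28 with an estimated correlation). Ythdc2 stood at 57.9 ± 4.94 and 160 ± 8.82 CPM and Smc1b at 159 ± 47.5 and 414 ± 23.0 CPM.

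Also at 120 h, 7 of 25 piRNA and germline genes were higher in KO, 0 lower and 18 did not pass (10 and 0 adjusted over the list alone; camera adjusted p = 0.00316, but adjusted p = 0.251 with an estimated correlation). Piwil4, which guides silencing of transposons, stood at 121 ± 9.37 and 38.5 ± 17.1 CPM. Of 18 glycolysis genes 5 were higher, 0 lower and 13 did not pass (9 and 0 adjusted over the list alone; camera adjusted p = 0.00118, but 0.371 with an estimated correlation). Pfkm stood at 57.3 ± 0.65 and 18.8 ± 0.19 CPM. Of 24 immediate early genes 6 were higher, 0 lower and 18 did not pass (7 and 0 adjusted over the list alone; camera adjusted p = 0.0053, but 0.251 with an estimated correlation). Nr4a1 changed by 1.54 ± 0.25. Of 14 myoid and stromal markers 4 were higher, 0 lower and 10 did not pass (4 and 0 adjusted over the list alone; camera adjusted p = 0.00113, but 0.251 with an estimated correlation). Col1a1 stood at 303 ± 0.90 and 83.4 ± 3.34 CPM. The count of 2702 became 604 without WT replicate 2, 597 without KO replicate 1, 1826 and 2408 without KO replicate 2 and WT replicate 1, and 494 with these groups compared alone, a setting that gave 1055 at 18 h. Stra8 lost its call without WT replicate 2 or either KO library (edgeR's quasi-likelihood test, Benjamini-Hochberg adjusted p up to 0.237).

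**Figure D4:**
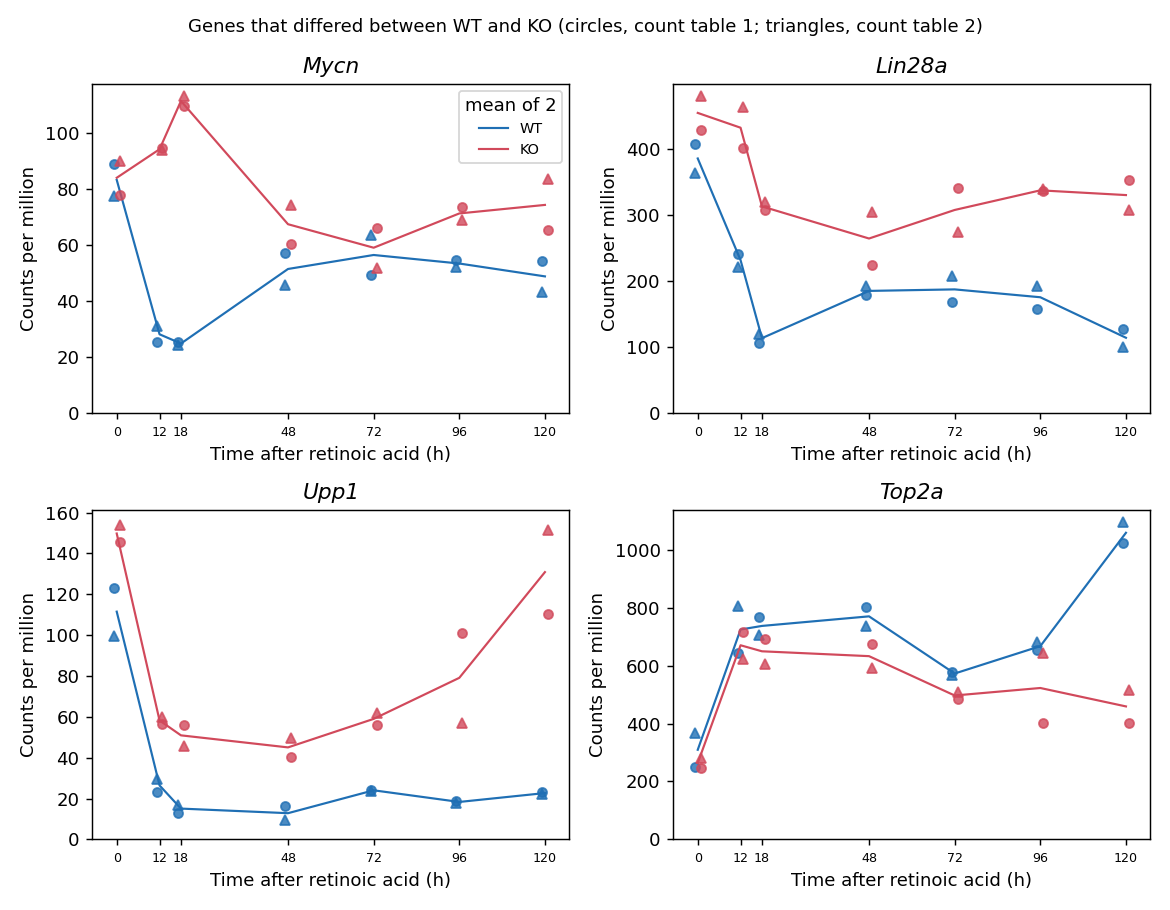
Mycn, Lin28a, Upp1 and Top2a (CPM) against hours in WT and KO, with each library as a point and lines through the group means. Values are per library total, and Mycn at 18 h lies at 109.8 and 113.3 CPM in KO and at 25.5 and 24.2 CPM in WT.

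Genotype by time interaction, the test of whether the course itself differs, called 19 genes. Mycn, a growth-promoting factor gene, fell in WT from 83.4 ± 5.85 at 0 h to 28.4 ± 3.97 at 12 h and 24.4 ± 1.09 CPM at 18 h, and in KO went from 82.7 ± 6.71 to 94.9 ± 1.00 and 115 ± 1.23 CPM (edgeR's quasi-likelihood test, Benjamini-Hochberg adjusted p = 0.00053). Rragd, a nutrient-sensing GTPase gene, fell in WT from 130 ± 18.6 to 17.4 ± 0.39 CPM at 18 h and in KO went from 111 ± 5.29 to 60.2 ± 2.10 CPM. The ubiquitin ligase subunit gene Fbxo40 went from 54.4 ± 13.9 to 3.45 ± 0.71 CPM in WT and from 67.5 ± 6.44 to 55.1 ± 9.51 CPM in KO at 18 h. Later differences were in Impdh1, of guanine nucleotide synthesis (33.7 ± 1.66 CPM in WT and 86.1 ± 15.5 in KO at 120 h), the RNA helicase gene Mov10 (118 ± 23.9 and 369 ± 51.1 CPM at 120 h), and Ccnd1, a G1 cyclin gene that shares 23.4% of its exon length with LTO1, which reached 372 ± 62.2 CPM in WT and 227 ± 57.6 in KO at 96 h. The remaining genes of the 12 with the smallest p were Abcd2, Pfkm, Smoc2, Plat, Tead2 and Aifm2. The count of 19 became 125 with limma on log2 CPM + 1 and the CPM table number as block. It was 81 with the replicate block, 268 with DESeq2 and 770 without a filter, and fell without the 3 shallow libraries. Leaving out WT 120 h replicate 2 (13) or KO 96 h replicate 1 (18) kept it within 1.5 times, and leaving out each of the other 26 libraries moved it further. Mycn and Rragd kept their calls without each of the 28 libraries in turn, and Fbxo40 lost its call without the WT 18 h replicate 1 (edgeR's quasi-likelihood test, Benjamini-Hochberg adjusted p = 0.0751). The other 9 of the 12 lost their calls without at least 1 library (edgeR's quasi-likelihood test, Benjamini-Hochberg adjusted p up to 0.199, for Aifm2). Of the 135 list calls in these comparisons, 7 held with an estimated correlation: the undifferentiated list in WT at 12 and 18 h, replication in WT at 12 h and in KO at 12, 48 and 96 h, and the differentiating list in KO at 96 h.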

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

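Of the tests in this part, the one of deviations shared between times and the alternatives with recovered reads and without the 3 shallow KO libraries were chosen after the result was seen.

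The course over time differed between the genotypes in 12 named genes, by a test of that difference (edgeR's quasi-likelihood interaction test, Benjamini-Hochberg; the value in brackets after each gene is the contrast of largest size, log2). Mycn had adjusted p = 0.00053 (2.25), Rragd adjusted p = 0.0038 (2.03), Fbxo40 adjusted p = 0.00404 (3.69) and Impdh1 adjusted p = 0.0162 (1.23). Abcd2 (3.22), Pfkm (1.23) and Ccnd1 (-0.89) each had adjusted p = 0.0329, and Smoc2 (2.03), Mov10 (1.48), Plat (2.26), Tead2 (1.12) and Aifm2 (1.23) each had adjusted p = 0.0373. Without the 3 shallow KO libraries, Mycn, Rragd, Fbxo40, Impdh1, Abcd2, Ccnd1 and Mov10 stayed under the threshold (edgeR, Benjamini-Hochberg adjusted p up to 0.0496) and Pfkm, Smoc2, Plat, Tead2 and Aifm2 did not (up to 0.14). Outside the gene counts, reads in no annotated gene made up 27.1 to 33.1% of WT libraries of the first count table, the highest at 0 h, and no value for KO stood in the tables beside it.

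The change since 0 h at 72, 96 and 120 h was smaller in KO than in WT. Values that use no shallow library argue against noise of these libraries as the whole cause. For genes chosen in the other WT libraries, the change in the deep KO libraries was 0.71, 0.55 and 0.33 of that in WT (0.80, 0.78 and 0.47 with recovered reads). With 1 library per genotype and time, these ratios have no spread between libraries. Over genes called in WT, the median ratio of KO to WT change was 0.45, 0.35 and 0.33 without the shallow libraries. It was 0.48, 0.43 and 0.37 with them. At 12, 18 and 48 h, where no library was shallow, it was also under 1, at 0.70, 0.59 and 0.58. These genes were picked by the same WT values that the ratio uses. Undifferentiated cells left in the KO sort stay open as a cause. At 120 h in the deep library, the share of RNA like that at 0 h was 0.71 (0.58 to 0.88) by the undifferentiated list. It was 0.77 (0.70 to 0.82) by the differentiating, replication and mitosis lists. In the shallow library these shares were 0.60 and 0.62. The ranges in brackets give no spread between libraries. Such close shares would also arise if every cell responded less by the same proportion. They therefore cannot tell left-over cells from a weaker response. The sort on the PIWIL2-eGFP reporter was the only one given, and whether it removes such cells was not tested. A weaker response of each cell without Stra8 was not tested and stays open.

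The 3 shallow KO libraries lay apart from the other 25, at 114.9 to 125.7 on the first principal component against -36.0 to 13.6. Depth is argued against for what the 3 share: their deviations from the recovered reads correlated between times at 0.57 to 0.58, and those of deep libraries thinned to the same totals at 0.08 to 0.19. For the rest low depth stays open, as thinned libraries correlated with the recovered reads only 0.021, 0.014 and 0.02 better than the shallow ones. GC content and transcript length together accounted for 8.7 and 9.3% of the variance, the lower at 96 h, and also stay open. At 72, 96 and 120 h, shallow minus recovered values correlated with length at 0.3, 0.29 and 0.3. With GC content they correlated at 0.01, 0 and -0.01, so the share goes with length rather than with a straight-line trend in GC content. Cells of another type may add to it and cannot be told apart here. Medians of shallow minus recovered values, averaged over the 3 times, were 0.16 for Sertoli and 0.16 for myoid markers. They were 0.04 for leukocyte and 0.23 for endothelial markers, with no list under 0. Whether the sort on the PIWIL2-eGFP reporter of germ cells removed such cells was not tested.

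The KO 48 h library of the first count table held 417 Stra8 reads, and its partner 7. WT cells or RNA in this library may be the source: over genes called in the mean comparison it lay 0.33 of the way from its partner to WT, against -0.32 to 0.12 at the other times, and Stra8 itself 0.41 of the way. Over genes with a 2-fold difference it lay at 0.20, beside 0.17 at 72 h, where Stra8 lay at -0.02, so the source stays open. A transcript made from the altered gene was not tested, because the part that the knockout lacks was not given in the sources used here.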

How the results depend on the processing

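The alternatives with recovered reads, without the 3 shallow KO libraries, with the KO numbers crossed in the block, with WT blocked alone and within each CPM table were chosen after the data were examined. Over all alternatives, tests of named genes kept their direction and side of the threshold in 5553 cases, lost a call in 552 (432 of them with 1 library left out), gained one in 17 and reversed in 17. Called lists kept their call in 600 cases, lost it in 205 (128 of them with an estimated correlation, 56 with fry and 12 without the 3 shallow KO libraries) and reversed in 5. Where an arm was left at 1 library, that library is assumed to vary like the other groups. In KO at 72, 96 and 120 h 1 of 2 libraries had 913055 to 1078460 reads, so that a count of 0 there allows up to 3.29 CPM. The values that follow are counts of called genes unless another quantity is named, and the cause was not tested.

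With 1 library left out in turn, KO vs WT gave 19 to 64 at 12 h, 176 to 356 at 18 h, 0 to 23 at 48 h, 86 to 737 at 72 h, 30 to 755 at 96 h and 597 to 2408 at 120 h. Against 0 h, WT gave 838 to 1339 at 12 h, 870 to 1533 at 18 h, 753 to 1603 at 48 h, 537 to 1645 at 72 h, 2409 to 4171 at 96 h and 2571 to 4452 at 120 h, and KO gave 346 to 944 at 12 h, 251 to 973 at 18 h, 35 to 430 at 48 h, 6 to 79 at 72 h, 17 to 222 at 96 h and 9 to 66 at 120 h. The KO time course gave 1809 to 2747 and the interaction 2 to 67. Stra8 was called at none of the last 3 times against 0 h in KO (edgeR's quasi-likelihood test, Benjamini-Hochberg). For Stra8, KO 72 h vs 0 h ranged over -0.60 to 0.52 on the log2 scale. For Stra8, KO 96 h vs 0 h ranged over -0.18 to 2.04, and for Stra8, KO 120 h vs 0 h ranged over -5.96 to 0.50.

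With the added 2-fold threshold, KO vs WT gave 1250 over the 7 times and 506 and 1625 at 72 and 120 h, WT 1453, 1368, 3045 and 3303 from 48 to 120 h, KO 955 and 974 at 12 and 18 h and the KO time course 1708. Without a filter, KO vs WT gave 73, 465 and 217 at 0, 12 and 48 h, KO 406, 552 and 387 from 72 to 120 h and the interaction 770. DESeq2 gave 322 and 108 for KO vs WT at 12 and 48 h, 291 and 505 for KO at 72 and 96 h and 268 for the interaction, with Stra8 in KO at 120 h at -0.19. With groups compared alone, KO vs WT gave 353, 1055, 75, 1, 0 and 494 from 12 to 120 h, WT 1006, 547, 2851 and 3192 at 12, 72, 96 and 120 h, and KO 2914, 3008, 2391, 15, 18 and 38 from 12 to 120 h. Leaving out mitochondrial and ribosomal protein genes gave 40 for the interaction. With a filter of 5 CPM in 2 libraries, WT and KO responses correlated across genes at 0.69, 0.65, 0.58, 0.67 and 0.62 at 12, 48, 72, 96 and 120 h. Within the second CPM table KO vs WT over the 7 times gave 1543, and Lars2, Mir6236, n-R5-8s1 and Yam1 turned to 0.06, 0.20, 0.11 and 0.37 on the log2 scale. With an estimated correlation, 7 of 135 list calls held.

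With the replicate block, KO vs WT gave 1, 315 and 86 at 0, 12 and 48 h, KO 237 and 532 at 72 and 96 h and the interaction 81. The block ended 3 list calls: replication in KO vs WT at 12 h, retinoic acid genes in KO vs WT at 72 h and immediate early genes in WT at 18 h (camera adjusted p = 0.056, 0.0508 and 0.0549). It changed no call of a named gene in the comparisons where they were named. With WT blocked alone, WT gave 2459, 2667, 3109, 2921, 5630 and 6094 from 12 to 120 h, and Stra8 gained calls at 72, 96 and 120 h. With the KO numbers crossed, KO vs WT gave 329 and 83 at 12 and 48 h, KO 1189 and 193 at 48 and 72 h and the interaction 100. With limma on log2 CPM + 1 and this block, KO vs WT gave 448, 1163, 113, 1971 and 1247 from 12 to 96 h, the KO time course 4868, KO 2498, 2602, 1660, 591, 1156 and 390 from 12 to 120 h and the interaction 125, with Stra8 in KO at 0.30 at 72 h and -0.10 at 120 h. On CPM + 0.1, KO vs WT gave 382, 1112, 105, 1865 and 1198, the KO time course 4593, KO 2288, 2426, 1458, 497, 1069 and 395 and the interaction 121, with Stra8 at 0.41 and -0.19.

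Without the 3 shallow KO libraries, KO vs WT at 72 h gave 135, the KO time course 1819, KO 7, 20 and 52 from 72 to 120 h and the interaction 7, with Stra8 in KO at 96 h at -0.18. Ribosomal protein genes, lower with all libraries, then tested upward (camera adjusted p = 0.00347 and 0.985 for KO vs WT at 72 and 120 h, and 0.544 and 9.89e-12 for KO against 0 h at 72 and 96 h). With recovered reads in their place, KO vs WT at 72 h gave 1414, KO 277 and 757 at 72 and 96 h and the interaction 56. The responses correlated at 0.51 at 120 h, Stra8 in KO at 72 h was 0.70 on the log2 scale, and ribosomal protein genes tested upward in KO at 96 h (camera adjusted p = 0.641).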

Other observations

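The tests of explanations in this part were written before the result was seen, apart from the splits that keep each numbered series whole. The list tests with recovered reads or without the 3 shallow KO libraries were chosen after.

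Of 15 genes of cell cycle inhibitors and cyclins D, 7 were higher and 3 lower in KO over the 7 times (7 and 3 adjusted over the list alone; camera adjusted p = 0.0748). Cdk4 (0.49 ± 0.08), Cdkn1b (0.80 ± 0.13) and Cdkn1a (0.73 ± 0.13) were higher and Rbl1 (-0.52 ± 0.09) lower (log2 and SE, 14 libraries per genotype). Of 20 p53 targets, 7 were higher and 1 lower (7 and 1 adjusted over the list alone; camera adjusted p = 0.209), and Sesn1 (0.51 ± 0.08) and Sesn2 (0.25 ± 0.07) were among the higher. Autophagy and lysosome genes went both ways, 9 of 36 higher and 8 lower (10 and 8 adjusted over the list alone; camera adjusted p = 0.722). Gabarapl1 (0.91 ± 0.07), Wipi1 (0.80 ± 0.08) and Sqstm1 (0.54 ± 0.06) were higher and Ulk2 (-0.51 ± 0.07) lower.

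Of 71 oxidative phosphorylation genes, 10 were higher and 3 lower in KO over the 7 times (7 and 1 adjusted over the list alone; camera adjusted p = 0.065), Sdhd (0.38 ± 0.08) among the higher. Of 76 cytosolic ribosomal protein genes, 3 were higher and 0 lower (2 and 0 adjusted over the list alone; camera adjusted p = 0.479), with Rps3 (0.33 ± 0.09) and Rpl4 (0.29 ± 0.10) among the higher. The ribosomal list tested downward with all libraries and upward both with recovered reads and without the 3 shallow ones (camera adjusted p = 0.0674 and 1e-05).

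For the mean KO vs WT count, libraries with the same number varied together over the times, and splits that keep each such series whole number 3, too few for a share under 0.05. The real one gave 6568 genes and the highest other, which follows the 2 CPM tables, 440. Of 40 splits that exchanged the libraries at each time independently, 1, the real one, gave as many genes, with 548 in the highest of the others.

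KO cells at 72 to 120 h may resemble an earlier WT time: the 3 deep KO libraries, 3 of 3, correlated best with WT at 0 h over genes of the WT time course (r = 0.63, 0.58 and 0.59, against 0.00, -0.06 and -0.01 with their own time), while 1 shallow library, at 96 h, correlated best with its own time (0.25). KO values were taken against the WT mean over the times, so steady genotype differences and a weaker response also enter here. The test cannot tell these from an earlier state. Measured from 0 h of each genotype without the shallow libraries, KO and WT changes at the same time correlated at 0.34, 0.40 and 0.34 across all tested genes. Genes lowered in WT by 12 h may be lowered less in KO: of 968 such genes 206 (21.3%) were higher in KO than WT at 18 h, against 2% of the others, a ratio of 10.42 (Fisher's exact test, p = 7.42e-121; genes are not independent). This compared KO with WT at 18 h, not KO with its own 0 h. Of 939 genes raised in WT by 12 h, 37 (3.9%) were lower in KO at 18 h, against 0.9% of the others. A further 46 of them (4.9%) were higher, against 3%, so raised genes went both ways. Variants of the knockout strain around Stra8 stay open as a source of calls there: within 10 Mb, 48 of 115 genes were called in the mean comparison (41.7%, against 37.4% elsewhere), a ratio of 1.12 (0.90 to 1.39; Fisher's exact test, p = 0.335).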
